A study of Homo sapiens with 4 samples.

How the data were processed

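In situ Hi-C was measured in 4 libraries, parental T47D, T47D-TamR, parental ZR75-1 and ZR75-1-TamR, with 1 library per group taken from the sample titles. Per the labels' protocols, nuclei were prepared and chromatin contacts captured by a published in situ Hi-C procedure. The submitters' processing notes name the build hg19. The aligner, the restriction enzyme, the interaction caller and its settings are not given in the sources used here. Other lines that the series' design text mentions were not analysed here.

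The authors' deposited lists have no header and 8 columns: 2 anchors with chromosome, start and end, a whole-number count and a score. The deposited count in column 7 was read as the number of read pairs that support an interaction, since its values are whole numbers of 5 or more. The deposited score in column 8 lies between 0 and 0.522, is generally lower at higher counts, though not at each step, and is fixed by the count within a library or, in parental T47D, within each of 2 sets of chromosomes (1 to 9, and 10 to X). Its kind is not stated, and it was used only as a filter in an alternative. A score of 0.05 or less reached down to a support of 15 in both parental libraries, 17 in T47D-TamR and 13 in ZR75-1-TamR. This filter therefore cut the 2 libraries of a pair at unequal support. Chromosomes are numbered in the lists, and number 23 was taken as X from its last listed position, 154904347. Coordinates are printed as listed, except that bins are counted from base 1.

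Anchors listed in reverse order (1.35% to 2.12% of interactions) were sorted, no interaction was listed more than once, and no filter was applied. The span is the distance between anchor midpoints. Chromosome shares were compared by the number of interactions, and 1 Mb bins by the number of interaction ends whose anchor midpoint lies in the bin. The log2 ratio of shares, TamR over parental, had 0.5 added to each bin count. Bins with fewer than 10 interactions over the pair were left out. Exact (Clopper-Pearson) 95% intervals of shares and ratios use interactions with at least 1 end in the bin, since both ends often share a bin. Fold limits against a count of 0 use a floor of 3 interactions per library and leave out the error of the other count. Interactions are listed only above a minimum support and neighbouring ones share fragments, so these intervals and floors cover counting error only and are narrower than the spread between cultures would be.

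Total support per library ranged from 5012562 to 9111888, and the number of reads sequenced is not given in the sources used here. A list that stops at a minimum support grows with depth, so that numbers and spans compared between libraries depend on it. Within a line no test between groups was possible with 1 library in each, and no p-value was computed for a bin or chromosome of a pair. A fit of resistance with the line as a block, over the interactions per bin in all 4 libraries with their totals as library sizes, was run with edgeR 4.0.16 and, on log2 shares with 0.5 added, limma 3.58.1 in R 4.3.3, and tested on simulated libraries with the common dispersion of that edgeR fit and 200 bins changed 4-fold. Bins were named by a rule fixed before the data were examined: per pair, the 5 highest and the 5 lowest by the bound of the interval nearest to no change, none within 5 Mb of one already named. Promoter classes, changes per gene and gene lists planned before the data were examined were not analysed here, because the gene table at hand is of assembly GRCh38.p14 and the lists are on hg19.

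A block is a run of at least 5 tested bins, with bins under the minimum passed over, whose running median over 5 bins lies beyond 1 or -1 on the log2 scale, a definition chosen after the bins were seen. The 2 pairs share no library, so that their bin ratios were correlated directly, with 1000 rotations of one profile along the genome as the comparison. Correlations over chromosomes used 100000 resamples. An interaction counted as shared if both anchors overlapped those of an interaction of the other library by at least 1 base, and the share was set against 20 random shifts of the second list along each chromosome. Clusters of interactions over 10 Mb were joined where both anchors lay within 2 Mb of those of another one.

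The interval and block routines were first tested on simulated data with the bins and library sizes of each pair and 200 bins changed by known folds. In the simulated T47D pair, with 2675 bins, 86.0% of bins raised 2-fold and 95.9% of those raised 4-fold had an interval beyond no change in the right direction. In the simulated ZR75-1 pair, with 2767 bins, these shares were 96.0% and 100%. Intervals held the simulated ratio in 96.4% and 96.2% of bins. Of 200 bins in 20 planted blocks changed 3-fold, 95.0% and 96.5% were found in blocks, with 3 and 2 unchanged bins beside them. Both simulated libraries of a pair were drawn from the parental profile, so unchanged bins had counting scatter only. Interval coverage and the number of unchanged bins in blocks therefore do not carry over to the real libraries. Shuffling the real bins put 58.7 bins in blocks on average in the T47D pair and 1.77 in the ZR75-1 pair.

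Alternatives planned before the data were examined were the better supported 0.5 of each list, the same number of interactions per pair, spans over 20 kb, summed support, 500 kb bins, a median weighted by support, and other overlaps. Alternatives chosen after seeing the data were a common minimum support of 7, binomial thinning of the deeper library to the same number of interactions, a score of 0.05 or less, shifts of 500 kb, blocks beyond 0.75, the fit with the line as a block, and removal of each chromosome's mean. Thinning kept each supporting read of T47D-TamR with a probability of 0.724 and of ZR75-1-TamR with 0.905. The work used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9.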

Results

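Chromatin contacts were mapped by in situ Hi-C, which joins and sequences DNA fragments that lie close together in the nucleus, in 4 libraries of human breast cancer cells. T47D and ZR75-1 are estrogen receptor alpha positive breast cancer lines whose growth depends on estrogen. Each was studied as the parental line and as a derivative resistant to tamoxifen (TamR), a drug that binds the estrogen receptor and blocks its action in breast cells. There was 1 library per group, so no difference within a line has a replicate check, and intervals cover counting error only. The series asks which promoter-distal contacts characterise tamoxifen-resistant cells. Gene annotation of the build of these coordinates was not used here, so regions are named by position on hg19 and not by gene. Each file listed pairs of anchors on the same chromosome with a supporting count, called support below.

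The libraries listed 303756 interactions in parental T47D, 457869 in T47D-TamR, 376001 in parental ZR75-1 and 572501 in ZR75-1-TamR. Their total support was 5012562, 9111888, 5100528 and 6849209. The median support per interaction was 10, 11, 8 and 7, and the lowest listed support was 7, 7, 6 and 5. All interactions were within a chromosome, on chromosomes 1 to 22 and X.

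In both lines the resistant library listed more interactions, and these reached farther. T47D-TamR listed 1.51 times and ZR75-1-TamR 1.52 times as many interactions as its parental library. The median span between anchor midpoints was 38.3 kb in T47D and 48.6 kb in T47D-TamR, a ratio of 1.27 (bootstrap 95% interval over interactions 1.26 to 1.27). In ZR75-1 it was 46.2 kb and in ZR75-1-TamR 55.8 kb, a ratio of 1.21 (1.20 to 1.21). Interactions of 100 kb to 1 Mb made up 15.4% of the T47D list (exact 95% interval 15.3 to 15.5) and 24.4% of the T47D-TamR list (24.3 to 24.6). The same class made up 23.1% (22.9 to 23.2) in ZR75-1 and 29.5% (29.4 to 29.7) in ZR75-1-TamR. Spans of 20 to 100 kb made up 82.9% and 74.1% in the T47D pair and 75.5% and 68.9% in the ZR75-1 pair. Spans under 20 kb made up 1.58% and 1.26% in the T47D pair and 1.31% and 1.36% in the ZR75-1 pair. Spans of 1 to 10 Mb were few, with 302 in T47D, 711 in T47D-TamR, 339 in ZR75-1 and 1130 in ZR75-1-TamR. With a common minimum support of 7, a setting chosen after the data were seen, the ratio of numbers in the ZR75-1 pair was 1.22. Both T47D lists start at 7, so that this minimum removes nothing from them.

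**Figure D1:**
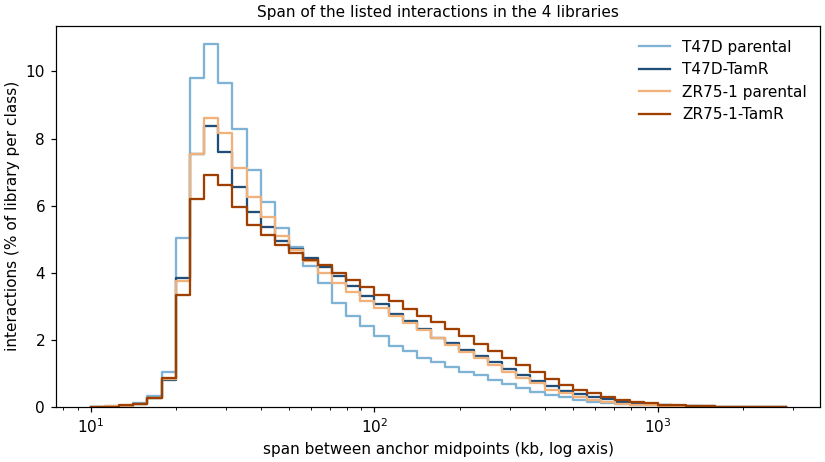
Share of each library's interactions (percent, vertical axis) by the distance between anchor midpoints (kb, log axis), 1 line per library. The TamR libraries have a smaller share in total at 20 to 100 kb and a larger one at 100 kb to 1 Mb than their parental libraries, with medians of 48.6 against 38.3 kb (T47D) and 55.8 against 46.2 kb (ZR75-1).

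Better supported interactions were shorter. In T47D the median span was 44.5 kb at a support of 7 to 9 and 30.6 kb at 50 or more. In ZR75-1-TamR it was 57.6 kb at a support of 7 to 9 and 36.3 kb at 50 or more.

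The distribution of interactions over the genome differed most in the T47D pair. Chromosome 13 held 2.22% of the interactions of T47D and 0.752% of those of T47D-TamR, a log2 ratio of -1.56 (exact 95% interval -1.62 to -1.50). This ratio was -1.96 in the better supported 0.5 of each list, -1.98 by summed support and -2.42 with a score of 0.05 or less. Chromosomes 5 and 11 were also lower in T47D-TamR, with log2 ratios of -0.67 (-0.69 to -0.64) and -0.65 (-0.68 to -0.62). Chromosomes 10, 16 and 17 were at -0.38, -0.38 and -0.37. Chromosome 6 held 5.88% of interactions in T47D and 10.3% in T47D-TamR, a log2 ratio of 0.81 (0.78 to 0.83). Chromosome 22 was at 0.89 (0.77 to 1.01), chromosome 20 at 0.60 (0.56 to 0.64) and chromosome 19 at 0.47 (0.33 to 0.60). Chromosome 21 was at 0.02 (-0.03 to 0.08), with an interval that included 0.

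In the ZR75-1 pair the resistant library held a smaller share on chromosomes 19, 22, 17 and 20. Their log2 ratios were -0.95 (-1.05 to -0.84), -0.79 (-0.85 to -0.72), -0.52 (-0.56 to -0.49) and -0.49 (-0.55 to -0.44). Chromosomes 16 and 1 were at -0.35 and -0.32. Higher shares were found on chromosome X, with a log2 ratio of 0.51 (0.46 to 0.56), and on chromosomes 4, 21 and 13, with 0.49 (0.46 to 0.51), 0.47 (0.38 to 0.56) and 0.43 (0.40 to 0.47). Chromosome X was at 1.21 by score and at 0.34 with equal numbers of interactions. Chromosome 11 was at 0.10 by number of interactions and at -0.28 by summed support.

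**Figure D2:**
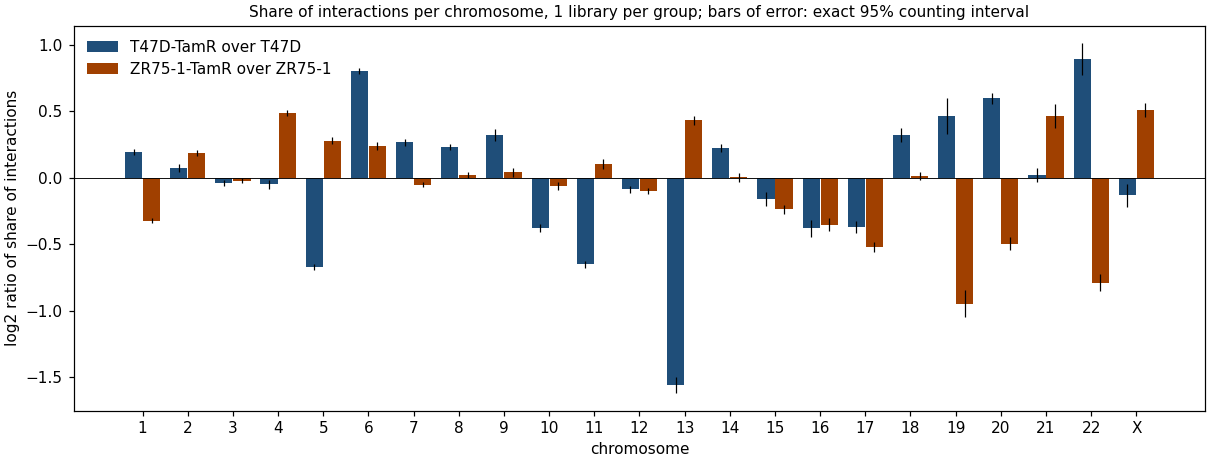
Log2 ratio of the share of interactions per chromosome (vertical axis), TamR over parental, for the T47D pair (blue) and the ZR75-1 pair (brown), with exact 95% counting intervals. Chromosome 13 lies at -1.56 in the T47D pair and at 0.43 in the ZR75-1 pair.

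Within chromosomes, the T47D changes came in long stretches. Of 2735 bins of 1 Mb with at least 10 interactions over the pair, 459 had a log2 ratio above 1 and 544 one below -1. Joined into blocks of at least 5 successive tested bins, passing over bins with fewer interactions, the raised stretches spanned 381 Mb in 23 blocks with 330 tested bins, and the lowered ones 431 Mb in 36 blocks with 415. The longest raised block took chromosome 1 from 1 to 73 Mb, with a log2 ratio of 1.51 over the block (SD over its 71 bins 0.73), and was followed by others at 78 to 99 Mb (1.32) and 101 to 106 Mb (1.27). On chromosome X, 57 to 123 Mb and 128 to 152 Mb were raised (2.03 and 1.72, with 38 and 13 tested bins), while 14 to 21 Mb and 24 to 44 Mb were lowered (-1.61 and -1.58). The whole chromosome X was at -0.13 although these stretches differed by more in opposite directions. Chromosome 8 was raised from its start to 14 Mb (1.93), chromosome 9 from 76 to 101 Mb (1.09) and chromosome 20 from its start to 26 Mb (1.34).

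The lowered blocks of the T47D pair took most of chromosome 13, at 20 to 67 Mb (-1.44) and 78 to 115 Mb (-1.98). Chromosome 2 was lowered at 175 to 189 Mb (-2.34), chromosome 3 at 83 to 96 Mb (-2.11) and chromosome 12 at 4 to 15 Mb (-2.87). Chromosome 5 was lowered at 82 to 104 Mb (-1.56) and 110 to 121 Mb (-1.90), chromosome 10 at 55 to 75 Mb (-1.45), and chromosome 11 at 37 to 43 Mb (-2.004). On chromosome 7 a raised block at 129 to 143 Mb (1.32) lay next to a lowered block at 144 to 159 Mb (-1.80).

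Single bins of the T47D pair went from nearly empty to well filled and the reverse. The first 1 Mb of chromosome 8 (bases 1 to 1000000) held 0 interactions in T47D and 65 in T47D-TamR, at least 14.1-fold higher against a floor of 3 interactions with the 65 taken as exact (log2 95% interval from 3.48 upward when the error of both counts is included). At 6 to 7 Mb of the same chromosome there were 2 and 123 (log2 ratio 5.18, 95% interval 3.44 to 8.38), and at 19 to 20 Mb 11 and 213 (3.60, 2.79 to 4.68). Bins at 81 to 82 Mb of chromosome 9 and 104 to 105 Mb of chromosome X each held 1 interaction in T47D and 74 in T47D-TamR (5.30 and 5.18, both with an interval of 3.07 to 10.91). In the other direction, 83 to 84 Mb of chromosome 13 went from 120 to 1 (-7.11, -12.84 to -5.02) and 108 to 109 Mb from 147 to 4 (-6.23, -7.71 to -4.43). At 5 to 6 Mb of chromosome 16 there were 47 in T47D and 0 in T47D-TamR, at least 24.1-fold lower against the floor of 3 with the 47 taken as exact (log2 95% interval from -4.23 downward with the error of both). Chromosome 5 at 117 to 118 Mb went from 198 to 11 (-4.71, -5.82 to -3.92) and chromosome 11 at 30 to 31 Mb from 371 to 31 (-4.31, -4.78 to -3.67).

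The ZR75-1 pair had fewer and shorter blocks. Of 2784 bins, 276 were above 1 and 147 below -1, and the SD of the bin values was 0.72 against 1.34 in the T47D pair. The number above 1 was 513 in the better supported 0.5 of each list, 491 by summed support and 681 with a score of 0.05 or less, where the T47D pair had 533. The score cut the 2 libraries of a pair at unequal support, lower in ZR75-1-TamR than in ZR75-1. Blocks spanned 193 Mb, of which 130 Mb in 13 blocks were raised. These included chromosome 1 at 71 to 84 Mb (1.33) and 102 to 108 Mb (1.75), chromosome 11 at 85 to 93 Mb (1.12) and 96 to 109 Mb (1.56), and chromosome 21 at 15 to 29 Mb (1.33). Chromosome 6 at 116 to 132 Mb (1.23) and chromosome X at 77 to 93 Mb (1.35) were raised as well. The 8 lowered blocks spanned 63 Mb, with chromosome 19 from its start to 7 Mb (-1.47) and from 9 to 20 Mb (-1.42), chromosome 9 at 130 to 141 Mb (-1.17), chromosome 16 at 85 to 90 Mb (-1.16) and chromosome 17 at 71 to 82 Mb (-1.11). The blocks of this pair spanned 405 Mb in the better supported 0.5, 426 Mb by summed support, 704 Mb by score and 121.5 Mb with 500 kb bins.

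**Figure D3:**
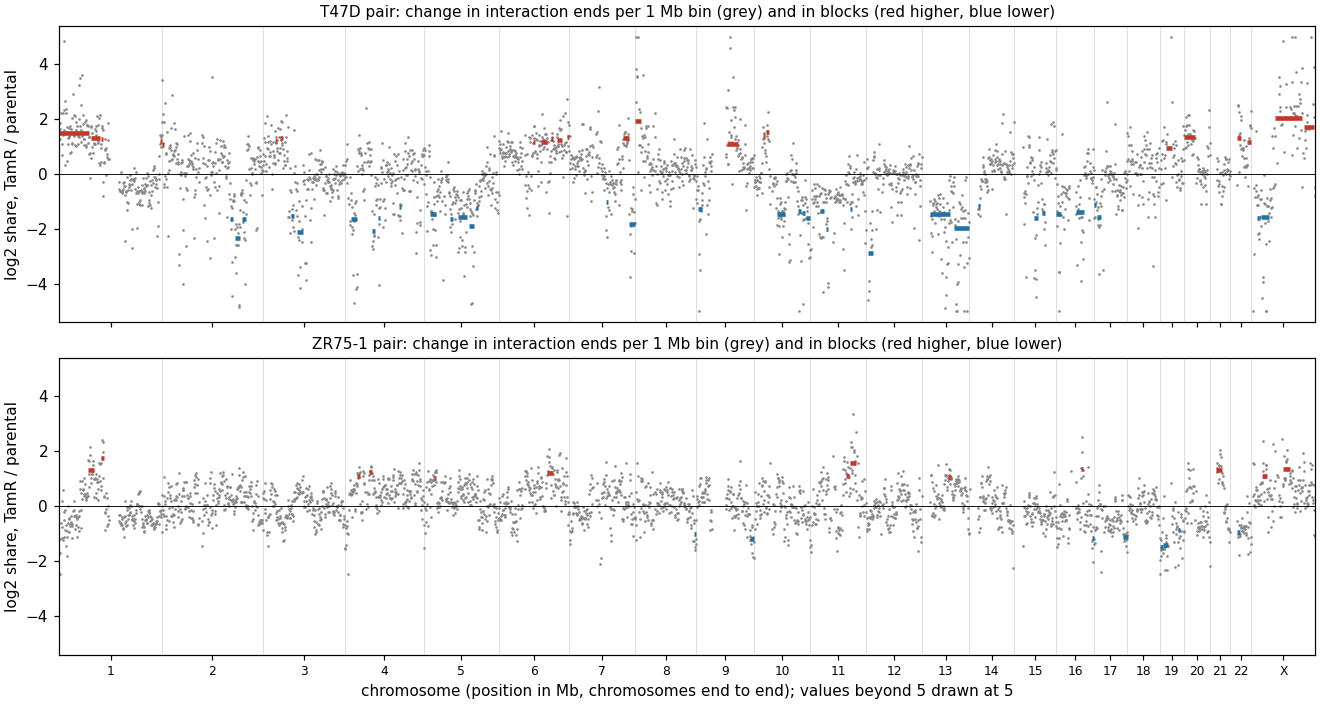
Log2 ratio of the share of interaction ends, TamR over parental (vertical axis), along the genome (horizontal axis, chromosomes end to end), per 1 Mb bin (grey) and over raised (red) and lowered (blue) blocks. The T47D pair (top) has 59 blocks over 812 Mb and the ZR75-1 pair (bottom) 21 blocks over 193 Mb.

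The named bin of the ZR75-1 pair with the most positive interval bound lay on chromosome 11 at 103 to 104 Mb, with 6 interactions in ZR75-1 and 103 in ZR75-1-TamR (log2 ratio 3.38, 95% interval 2.30 to 4.95). In order of that bound, chromosome 1 at 105 to 106 Mb had 12 and 100 (2.34, 1.56 to 3.43), chromosome X at 27 to 28 Mb 12 and 99 (2.38, 1.55 to 3.41), chromosome 11 at 97 to 98 Mb 11 and 85 (2.34, 1.41 to 3.38) and chromosome 21 at 23 to 24 Mb 27 and 152 (1.91, 1.27 to 2.51). The most negative were at 62 to 63 Mb of chromosome 20, from 70 to 23 (-2.19, -2.98 to -1.54), and at 105 to 106 Mb of chromosome 14, from 57 to 18 (-2.23, -3.15 to -1.51). Bins at 8 to 9 Mb of chromosome 4 (37 to 10, log2 ratio -2.47), 137 to 138 Mb of chromosome 9 (93 to 38, -1.86) and 17 to 18 Mb of chromosome 19 (33 to 10, -2.33) followed.

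Along the genome, the changes of the 2 backgrounds ran weakly against each other. Over 2714 bins the log2 ratios of the 2 pairs had a Pearson r of -0.15 and a Spearman rho of -0.13. This is a correlation across bins, which are not independent replicates. The bin ratios also followed a density of anchor boundaries, with opposite signs in the 2 pairs. For each pair this density was measured in the libraries of the other background, so the 2 trends are not along 1 shared measure. The Spearman rho with it was -0.19 in the T47D pair and 0.22 in the ZR75-1 pair. Rotating a profile breaks its relation to its density too. The rotations below therefore cannot tell density trends of opposite sign apart from other opposite changes. None of 1000 rotations of one profile against the other gave an r as far from 0, and 95% of them lay between -0.10 and 0.08 (two-sided permutation p = 0.001, the smallest they can give, and 0.003 after Benjamini-Hochberg adjustment over 3 relations). Bins above 1 in both pairs numbered 47, with 42.4 expected of independent lists, and bins below -1 in both numbered 15, with 26.5 expected. Bins lower in T47D-TamR and higher in ZR75-1-TamR numbered 93, with 51.0 expected, and those with the opposite pattern 32, with 22.0 expected. Across the 23 chromosomes r was -0.41 (permutation p = 0.042, adjusted 0.063) and rho -0.28 (permutation p = 0.197, adjusted 0.197). Without chromosomes 22 and 13, the farthest from the median in the T47D pair, r was -0.18, so the relation over chromosomes rested on them.

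The 2 lines were also taken as a block in a fit of resistance over all 4 libraries, chosen after the data were seen. With 1 residual degree of freedom, edgeR's quasi-likelihood test called 0 of 2714 bins at a Benjamini-Hochberg adjusted p under 0.05 (lowest adjusted p 0.998) and limma called 0 (0.999). At an unadjusted p under 0.05 there were 25 bins by edgeR and 33 by limma, each fewer than the share of 0.05 expected with no change. In simulated libraries with the common dispersion of the edgeR fit, edgeR found 20.5% and limma 33.5% of 200 bins changed 4-fold, so that most such changes would be missed.

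The 2 libraries of a line resembled each other more than those of different lines. The Spearman correlation of interaction ends over 2834 bins was 0.77 between T47D and T47D-TamR and 0.88 between ZR75-1 and ZR75-1-TamR. Across backgrounds it lay between 0.48 (T47D-TamR and ZR75-1-TamR) and 0.63 (T47D and ZR75-1-TamR).

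Few single interactions were listed in both libraries of a pair. Both anchors of 19.0% of T47D interactions (exact 95% interval 18.9 to 19.1) overlapped those of an interaction in T47D-TamR, against 12.8% ± 0.294 (SD, 20 random shifts along the chromosomes), a ratio of 1.49. Of ZR75-1 interactions, 21.9% (21.8 to 22.0) were found in ZR75-1-TamR, with 14.6% ± 0.511 after shifting and a ratio of 1.50. Between the parental lines, 16.1% of T47D interactions were found in ZR75-1, with a ratio of 1.37. After shifts of only 500 kb, which keep the regional density and were chosen after the data were seen, these 3 ratios were 1.23, 1.22 and 1.17. In the better supported 0.5 they were 1.83, 1.88 and 1.66, and by score 2.24, 2.85 and 2.21, both against the random shifts. Exactly the same anchors were listed in both libraries for 9.20% of T47D and 7.57% of ZR75-1 interactions. With anchors allowed to lie within 20 kb of each other, 91.8% and 96.1% were found in the TamR library. The ratio to random shifts was only 1.41 for T47D at this tolerance, so most of such matches also arise after shifting. The raw shares alone do not rank the libraries by likeness. With overlapping anchors, 19.6% of T47D interactions were found in the longer ZR75-1-TamR list, more than in T47D-TamR. Random shifts of that list gave 14.4%, a ratio of 1.36.

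The interactions with identical anchors in all 4 libraries numbered 1312, with a median span of 28.0 kb. Chromosome 1 held 199 of them, chromosome 8 held 128 and chromosome X held 1. The 1 Mb bin with the most was at 8 to 9 Mb of chromosome 7, with 12. The interaction whose lowest support over the 4 libraries was highest joined bases 145000519 to 145001027 with 145023341 to 145025990 of chromosome 1, with a support of 268 in T47D, 295 in T47D-TamR, 387 in ZR75-1 and 304 in ZR75-1-TamR. Another, on the same chromosome, joined 182564946 to 182567655 with 182752978 to 182756041, with a support of 305, 242, 600 and 849. Both anchors of the first lie within bases 144922231 to 145118553 of chromosome 1. That stretch is 1 side of a cluster of interactions over 10 Mb found in both backgrounds. Repeats or reference errors are not argued against there.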

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

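The tests of the minimum support in the second pattern and of blocks built from short spans in the first were chosen after the result was seen. The results below moved in opposite directions in the 2 backgrounds, with intervals that exclude no change in both, and the difference was not tested. The trends of the 2 pairs with their densities of anchor boundaries, which had opposite signs, were not removed from these results.

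Chromosome 13 had a log2 ratio of -1.56 in the T47D pair and 0.43 in the ZR75-1 pair, a difference of -1.99. Chromosomes 22, 19 and 20 were higher in T47D-TamR (0.89, 0.47 and 0.60) and lower in ZR75-1-TamR (-0.79, -0.95 and -0.49), differences of 1.68, 1.41 and 1.09. Chromosome 5 was at -0.67 and 0.28 (difference -0.95), chromosome 11 at -0.65 and 0.10 (-0.75), chromosome X at -0.13 and 0.51 (-0.64) and chromosome 4 at -0.05 and 0.49 (-0.54). Chromosome 1 was at 0.19 and -0.32 (0.51) and chromosome 7 at 0.27 and -0.05 (0.32). The opposite direction was lost for chromosome 11 by summed support and by score (ZR75-1 at -0.28 and -0.037), for chromosome 4 in the better supported part and by score (T47D at 0.043 and 0.13), and for chromosome 7 by summed support (ZR75-1 at 0.025). Of the 23 chromosomes, 13 had log2 ratios of the same sign in both pairs. The difference was not tested for any chromosome, since each group had 1 library.

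Among the named bins, which were the 5 highest and the 5 lowest of each pair, 9 moved in opposite directions. The first 1 Mb of chromosome 8 was at 3.82 in the T47D pair with the floor of 3 in place of the 0 parental interactions (lower 95% limit 3.48), and at -1.23 in the ZR75-1 pair (difference 5.05 with that floor and without the error of the other counts). Chromosome 13 at 83 to 84 Mb was at -7.11 and 0.91 (-8.02) and at 108 to 109 Mb at -6.23 and 0.39 (-6.62). Chromosome 5 at 117 to 118 Mb was at -4.71 and 0.90 (-5.61). Chromosome 11 was at -4.31 and 0.59 (-4.90) at 30 to 31 Mb and at -1.995 and 2.34 (-4.33) at 97 to 98 Mb. Chromosome X at 27 to 28 Mb was at -3.94 and 2.38 (-6.32), chromosome 20 at 62 to 63 Mb at 1.13 and -2.19 (3.32) and chromosome 9 at 137 to 138 Mb at 0.57 and -1.86 (2.43). Again the difference was not tested.

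The first pattern weighed is the long blocks, which held 745 bins in the T47D pair and 190 in the ZR75-1 pair. Shuffling the bins 1000 times gave at most 131 and 15 bins in blocks, which argues against scatter of single bins. After thinning to equal numbers of interactions, 84.8% of the T47D block bins were still beyond 1, against 85.2% before. This argues against the number of listed interactions as the cause of most T47D block bins. In ZR75-1 66.3% were still beyond 1, against 81.6% before. Thinning did not make the reads sequenced equal, so depth stays open in both pairs. After the trend with the density of anchor boundaries was removed, 77.7% and 67.4% stayed beyond 1, so that restriction site density stays open for part of the block bins. The boundaries are those of listed interactions in the other background, and measure restriction sites only indirectly. Of the block bins, 83.5% in T47D and 96.3% in ZR75-1 moved the same way at 20 to 50 kb and over 100 kb. This decides nothing, since they were chosen on these same interactions. Of the bins of blocks built from 20 to 50 kb alone, 96.5% of 254 and 98.6% of 70 moved the same way over 100 kb, so these blocks held across spans. The share was 76.3% and 80.8% of bins outside. Those bins are by definition mostly nearer to no change, so lower agreement there decides nothing. Agreement across spans does not separate a change in segment amount from a regional change in contacts. In T47D the support of interactions with identical anchors had a median log2 ratio of 0.91 in raised blocks, 0.32 outside and -0.19 in lowered ones. Whole segments changed in amount, as a copy number difference may give, would move it in this direction. These interactions come from the lists that defined the blocks, and a regional change in contacts could move their support the same way. In ZR75-1 the medians were 0.00, 0.00 and -0.37. A change of whole segments therefore cannot be told apart from a change in contacts in either pair. Selection under tamoxifen and drift between cultures remain untested.

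The second pattern is the larger number and longer span of interactions in the TamR libraries. The lowest listed support was 7 in both T47D lists, so a lower minimum cannot account for the ratio of 1.51 there, and with a minimum support of 7 the ratio was 1.22 in the ZR75-1 pair, where a lower minimum could account for part. Total support over the listed interactions was 1.82 times the parental value in T47D-TamR and 1.34 times in ZR75-1-TamR. Depth therefore stays open for the larger number of interactions in both pairs. The ratio of median spans after thinning was 1.15 in the T47D pair, which argues against the number of listed interactions as the whole cause, and 1.09 in the ZR75-1 pair. Thinning made the numbers of interactions equal and not the reads sequenced, so depth stays open for the span in both pairs. Outside the blocks the ratios were 1.28 and 1.22, so that the blocks are unlikely to account for the longer spans. The number of reads sequenced was not used here, and a biological change in contact range tied to resistance remains an untested explanation.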

How the results depend on the processing

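The minimum support of 7, thinning, the score of 0.05 or less, the 500 kb shift, the 0.75 block bound, the fit with the line as a block and the removal of chromosome means were chosen after the data were seen. The paired fit with the line as a block called 0 bins with edgeR and 0 with limma, at 1 residual degree of freedom. Promoter windows, gene scaling, gene minimum and other gene alternatives were not run. Leaving out the minimum of 7 in T47D, which removes nothing there, all 130 alternative values of the named bins kept their sign and stayed beyond 1 (smallest size 1.65), but 16 left their interval, each to a larger size, as chromosome 5 at 117 to 118 Mb (-8.43 by score), chromosome 11 at 30 to 31 Mb in T47D (-7.24 by score) and at 97 to 98 Mb in ZR75-1 (4.15 in the better supported part, 4.51 by score). Of the values below and their like, 57 moved by less than their interval or 1.5 times, 62 moved by more, and 9 more came from settings that could not move them (the minimum of 7 in T47D, and the ratio of numbers between equal parts of the lists); the cause was not tested except where fewer interactions were used. Of the chromosome values, 130 stayed within their interval, 158 left it with the same sign (the farthest by score, chromosome 13 in T47D at -2.42 and X in ZR75-1 at 1.21), and 23 could not move. In all, 12 changed sign, 1 of them (chromosome 21 in T47D, -0.017 by score) with an interval that included 0; the other 11 were by summed support chromosome 2 in T47D (-0.0032) and 3, 7 and 11 in ZR75-1 (0.081, 0.025 and -0.28); in the better supported part chromosome 4 in T47D (0.043) and 3 in ZR75-1 (0.0077); by score chromosome 4 in T47D (0.13) and 3 and 11 in ZR75-1 (0.075 and -0.037); and chromosome 2 in T47D with equal numbers (-0.021) and thinning (-0.025). The ratio of numbers was 1.42 in T47D and 1.63 in ZR75-1 by score, and 1.22 in ZR75-1 with a minimum of 7. Values by score compare lists cut at unequal support, higher in T47D-TamR and lower in ZR75-1-TamR than in the parental library. The ratio of median spans in T47D and ZR75-1 was 1.18 and 1.14 in the better supported part, 1.14 and 1.08 with equal numbers, 1.15 and 1.09 after thinning, 1.12 and 1.06 by score and 1.104 and 1.112 weighted by support, and 1.12 in ZR75-1 with a minimum of 7. ZR75-1 bins above 1 numbered 513 in the better supported part, 681 by score and 491 by summed support, and its blocks spanned 405, 704 and 426 Mb, 121.5 Mb with 500 kb bins and 506 Mb beyond 0.75. The correlation of the 2 pairs over bins was -0.19 with equal numbers and -0.19 after thinning, and -0.12 without chromosome means. The shared percent of T47D in T47D-TamR, ZR75-1 in ZR75-1-TamR and T47D in ZR75-1 was 9.20, 7.57 and 5.98 with identical anchors, 91.8, 96.1 and 87.1 within 20 kb, 15.7, 17.8 and 12.3 in the better supported part, 15.2, 17.4 and 13.4 with equal numbers, 15.0, 17.5 and 12.8 after thinning, and 13.0, 13.6 and 7.35 by score; with a minimum of 7 it was 16.4 and 12.2 for the last 2. The ratio to shifted lists was 1.23, 1.22 and 1.17 with the 500 kb shift, 1.83, 1.88 and 1.66 in the better supported part, 1.55, 1.55 and 1.42 with equal numbers, 1.56, 1.56 and 1.46 after thinning, 2.24, 2.85 and 2.21 by score, 1.77 and 1.43 for the last 2 with a minimum of 7, and 1.41 for the first within 20 kb. Depth limits single bins: a parental count of 0 bounds a change only from below, and a count of 1 leaves a wide interval.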

Other observations

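All tests of the clusters and of sharing by support were chosen after the data were seen.

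A small number of interactions spanned over 10 Mb: 35 in T47D, 86 in T47D-TamR, 58 in ZR75-1 and 157 in ZR75-1-TamR. Of these 336, 263 fell into 14 clusters of at least 5. In the T47D background the fullest joined 31.5 Mb and 83.2 Mb of chromosome 7, with 11 interactions in T47D and 27 in T47D-TamR, and 17.4 Mb and 75.8 Mb of chromosome 9, with 11 and 18. A further one on chromosome 9 joined 77.9 Mb and 106.3 Mb, with 5 and 5. In the ZR75-1 background the fullest joined 113.2 Mb and 168.3 Mb of chromosome 6, with 14 interactions in ZR75-1 and 46 in ZR75-1-TamR, and 13.4 Mb and 64.5 Mb of chromosome 12, with 15 and 20. Chromosome 8 at 114.3 Mb and 128.7 Mb had 2 and 9, chromosome 12 at 55.7 Mb and 83.4 Mb had 1 and 10, and chromosome 1 at 188.9 Mb and 242.9 Mb had 1 and 9. The best supported interaction of the chromosome 6 cluster had a support of 55, and that of the chromosome 7 cluster 50.

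The third pattern weighed is these clusters. Re-pairing the anchors of the long interactions within each chromosome gave up to 15 clusters of at least 5, as many as the 14 seen, but most of these interactions are cluster members, so that re-pairing rebuilds the clusters and decides nothing; a draw of the same number of pairs from all anchors, run as a second test, gave at most 2, which argues against chance pairs of distant fragments. Interactions of 1 background only made up 92.9% of the clusters (13 of 14), which argues against repeats or reference errors except at 120.5 Mb and 145.1 Mb of chromosome 1, which had 10 interactions in T47D-TamR, 4 in ZR75-1 and 11 in ZR75-1-TamR. Junctions of rearranged segments carried by a line, parental and resistant alike, may account for the others, since 100% of clusters had interactions in both libraries of the background that held most of them. Support had no common trend with distance from the best supported interaction in the 9 clusters of at least 10 (median Spearman rho -0.010, below 0 in 5), where a junction is expected to give such a fall, so this hypothesis cannot be told apart from a long-range contact particular to the line.

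Sharing between the libraries of a line, set against 500 kb shifts, was closest to the shifted share among the best supported interactions of the first list. Only that list was split by support, and the second was used whole. The ratio rose and then fell with support: at a support of 7 to 9, 16.3% of T47D interactions were found in T47D-TamR, a ratio of 1.16, at 10 to 19 20.2% (1.28), at 20 to 49 22.8% (1.27) and at 50 to 99 21.8% (1.16). Exactly the same anchors were listed for 7.41% at 7 to 9. At a support of 100 or more, 19.3% (exact 95% interval 17.9 to 20.7) of 3147 T47D interactions were shared with T47D-TamR, against 18.5% after 500 kb shifts, and 22.9% (21.5 to 24.4) were shared with ZR75-1, against 17.2%. Of 3258 such ZR75-1 interactions, 20.8% (19.4 to 22.2) were shared with ZR75-1-TamR, against 18.9%, and 23.2% (21.7 to 24.7) with T47D, against 13.2%. By identical anchors the order was the other way for T47D at this support, with 15.0% of its interactions listed in T47D-TamR and 13.4% in ZR75-1. For ZR75-1 the shares were nearly equal, with 15.8% of its interactions listed in ZR75-1-TamR and 15.6% in T47D. The support of interactions with identical anchors in both libraries of a pair had a Spearman correlation across interactions of 0.28 in the T47D pair (27935 interactions) and 0.30 in the ZR75-1 pair (28482).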
